A study of Mus musculus with 18 samples.

How the data were processed

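RNA sequencing was done on 18 libraries from 7 populations of mouse thymocytes, the developing T cells of the thymus. Per the labels' protocols, about 10000 cells of each population were sorted from the thymus of C57BL/6 mice at postnatal day 10. The cells were lysed directly, RNA was amplified into cDNA with a NuGEN Ovation kit, and 1 ng of amplified cDNA went into each library for Illumina HiSeq sequencing. The populations are named DN1ab (n = 2), DN1d (n = 2), DN1e (n = 3), ImmV2 (n = 2), DN1 ckit+ (n = 3), DN2 (n = 3) and DN4 (n = 3) in the labels. DN stands for double-negative thymocytes, which lack the coreceptors CD4 and CD8. The name ImmV2 is not expanded in the sources used here. The design text speaks of biological replicates and names ImmV2 as the population the others can be compared with. No label says that replicates came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical.

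The values deposited by the authors are log2 FPKM for 34082 gene symbols, with 1 row per symbol. The submitters' processing notes name the aligner Bowtie and the mouse genome build mm8. The aligner version, annotation, quantifier and normalization are not given in the sources used here, nor is the way several transcripts of a gene were reduced to 1 row. The lowest value in the deposited log2 table corresponds to 0.01 FPKM in every library, and 477 rows had it in all libraries. At the ranks compared, down to 10000 from the top, the sorted values of the libraries lay close together, those of DN4 3 less so, while the number of rows at the lowest value ranged from 11746 to 18272. Different genes carried the same value in different libraries, such as 20440 FPKM for Tcrg-V7 in ImmV2 1 and Traj61 in ImmV2 2. Actb in DN4 2, Hsp90ab1 in DN4 1 and Traj57 in ImmV2 2 all had 965.4 FPKM. High values thus appear to have been put on a shared scale by rank before deposit, by a method not given. They would then reflect a gene's rank in its library, and quantile normalization as an alternative could change little. The table holds no counts, so the depth of the libraries is unknown and no counting interval is given. The reference annotation held here is of another build than mm8, so no coordinates are printed.

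Each library had between 34.5% and 53.6% of rows at the lowest value. Genes that every cell uses were among them or close to it: Actb was under 1 FPKM in 11 libraries, Eef1a1 in 8 and Hsp90ab1 in 10. The 10 highest rows held 75.4% to 82.3% of summed FPKM. A gene at the lowest value is therefore only said to be listed at the lowest value. Values are given per library rather than as mean and SD, and no difference is given against a population whose libraries are all at the lowest value.

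Deposited values were converted to FPKM, a pseudocount of 1 FPKM was added and log2 taken again. A log2 difference on this scale understates the change of low genes. The 24525 genes with at least 1 FPKM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend). All 18 libraries entered one fit of population means, so that small groups shared an estimate of the spread. Tests were two-sided with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05 with an absolute log2 difference of at least 1. The 11 comparisons were each of 6 populations against ImmV2 and 5 pairs within the double-negative series. A moderated F test compared the 7 populations at once.

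The comparisons, the 18 gene lists, the rule for named genes and all but 2 of the alternatives were fixed before the data were examined. The text may name 18 key genes, 1 of which is not reported here. The others are Sox13, Sox4, Maf, Blk, Tcf7, Lef1, Kit, Il7r, Zbtb16, Bcl11b, Gata3, Id2, Id3, Cd3e, Cd24a, Cd44 and Il2ra. It may also name the 6 called genes with the largest and the 6 with the smallest log2 difference among those whose values do not overlap between the populations, passing over RIKEN clones, Gm and LOC names, microRNAs, small nucleolar RNAs and unnamed rows. Up to 4 called members of each list and the T cell receptor gene segments complete the rule. Clone-based accession names were read as unnamed rows after the values had been seen. List members that passed only when adjusted over the list alone fall outside the rule and were named after their values were seen, as were housekeeping and macrophage genes. Segment names were matched without regard to case, and Tra2a, Tra2b and Tradd, which are not receptor genes, were removed. Spi1, Zfpm1 and Irf8 were not analysed here.

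The lists were a programme of IL-17-producing gamma delta T cells (Tgd17), HMG-box factors, type 1 and cytotoxic effector genes, innate lymphoid genes, early progenitor genes, T-lineage commitment factors, Notch targets, the T cell receptor (TCR) complex and proximal signalling, TCR signal-induced genes, the double-positive transition, cell cycle, trafficking receptors, and immediate early and stress genes. Markers of other cells were listed for B cells, myeloid cells, dendritic and plasmacytoid cells, erythroid cells and thymic epithelium. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 18 lists within a comparison, and again with an estimated correlation. Shares of other cell types in the sorts were not measured.

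The procedure was tested on simulated data built from the real gene means and residuals, with 50 genes changed at each size. Residuals were shuffled within each gene over all libraries, so every population had the same spread. In the data a gene could lie at the lowest value throughout some populations and vary in others, as Traj35 did. The simulation leaves that out, so its numbers may not hold for the data. For DN1d vs ImmV2, a log2 change of 4 was recovered for 8 of 50 genes and a change of 8 for 38 of 50, while 10 unchanged genes were called. For DN4 vs DN2, the same sizes were recovered for 20 of 50 and 42 of 50, while 7 unchanged genes were called. Alternatives changed the pseudocount, the filter, the scaling, the libraries in the fit, the trend, the threshold and the replicate block, and left out each library in turn. Figures were drawn with matplotlib 3.10.9.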

Results

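Transcript levels were measured in 18 RNA-seq libraries from 7 sorted thymocyte populations of mice at postnatal day 10, in a series on progenitors of Tgd17 cells, the gamma delta T cells that make IL-17. DN1 to DN4 are successive stages before CD4 and CD8 appear, and DN1 ckit+ cells carry the stem cell factor receptor Kit. Rank correlations across genes were low. The Spearman correlation between libraries of 1 population had a median of 0.325 (15 pairs, 0.251 to 0.390), against 0.243 between populations (138 pairs, 0.161 to 0.350). The difference of the means was 0.0693, with a one-sided permutation p of 1e-05 over library labels, the smallest the permutations could give. Genes are not independent replicates in these correlations. Of the 18 libraries, 14 had their highest correlation with a library of their own population. By that rule DN1ab 2 matched DN1 ckit+, both DN1d libraries matched ImmV2 2, and ImmV2 2 matched DN4. Margins could be small: DN1d 2 had 0.255 with ImmV2 2, 0.251 with DN1d 1 and 0.239 with ImmV2 1.

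The 7 populations differed at 343 genes in limma's moderated F test (Benjamini-Hochberg adjusted p under 0.05), with 2772 genes at an unadjusted p under 0.05. Bcl11b, a transcription factor needed for T-lineage commitment, was at 13.3 to 61.9 FPKM in every DN1d, ImmV2, DN2 and DN4 library and at 0.217 FPKM or less in every DN1ab and DN1 ckit+ library. In DN1e its log2 difference from ImmV2 was -3.46 ± 0.96 SE (adjusted p = 0.145, limma), against -4.89 in DN1ab and -5.03 in DN1 ckit+. Sox13, an HMG-box factor linked to Tgd17 cells, was at 14 and 76.3 FPKM in DN1d and at 7.15 and 11.3 FPKM in ImmV2. Sox13 passed the test over all genes in none of the 11 comparisons. The comparisons called between 15 and 147 genes. How these divided into higher and lower genes was not firm: the share higher in a population was larger when 1 of its own libraries was left out, except without DN4 2 in DN4 vs DN2, and smaller when 1 of the other population's was. All of these calls rest on a spread shared among the populations. With only the libraries of the compared populations in the fit, limma called 0 genes in 9 comparisons, with 1043 to 1830 genes at an unadjusted p under 0.05, and 5 of the 128 calls of genes named by the rule held.

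**Figure D1:**
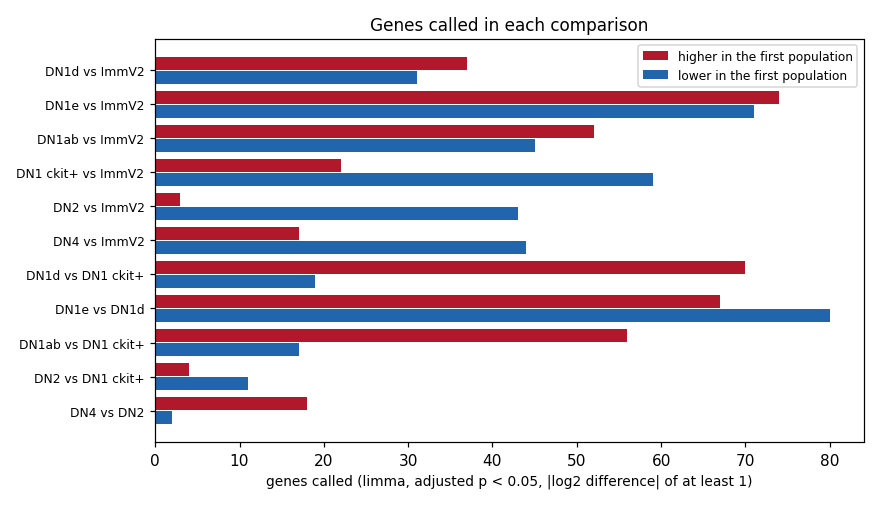
Bars show the number of genes called by limma in each comparison, split into genes higher (red) and lower (blue) in the first-named population, on a linear axis from 0. DN1e vs DN1d had the most calls, 147, and DN2 vs DN1 ckit+ the fewest, 15. The comparisons of 3 against 3 libraries, DN2 vs DN1 ckit+ and DN4 vs DN2, had the fewest calls, and the counts are no measure of distance.

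**Figure D2:**
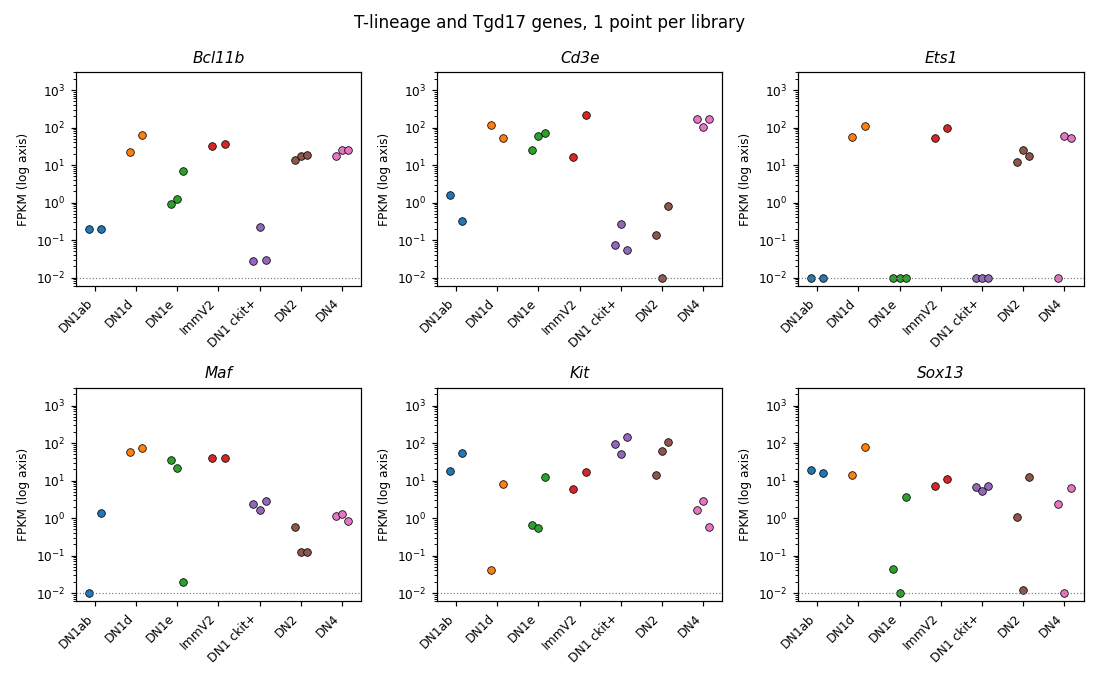
Each point is the FPKM of 1 library on a log axis, for 6 genes in the 7 populations, and the dotted line marks the lowest listed value, 0.01 FPKM. Bcl11b lies at 22.2 and 61.9 FPKM in DN1d and at 0.217 FPKM or less in DN1 ckit+.

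DN1d was compared with ImmV2, the reference population. Maf, a transcription factor of Tgd17 cells, was at 56.1 and 75.6 FPKM in DN1d and 39 and 40.7 FPKM in ImmV2 and did not pass (adjusted p = 1, limma). Among called genes, the immunoglobulin kappa constant gene Igkc was at 843 and 1205 FPKM in DN1d and 2.08 and 0.01 FPKM in ImmV2 (log2 difference 9.16 ± 1.47 SE, adjusted p = 0.00877, limma). Dio3, a thyroid hormone deiodinase, was listed at the lowest value in both DN1d libraries and at 333 and 119 FPKM in ImmV2 (adjusted p = 0.000605, limma). Trdv4, a delta chain variable segment, was at 19.6 and 32.8 FPKM in DN1d and 0.01 and 0.705 FPKM in ImmV2 (log2 difference 4.33 ± 0.60 SE, adjusted p = 0.00388, limma). In total 68 genes were called, 37 higher and 31 lower in DN1d. The B cell list was higher in DN1d (camera adjusted p = 0.0164, 10 members tested, 0 called, also 0 adjusted over the list alone), with adjusted p = 0.0956 with an estimated correlation. Its member Cd79a, chosen after its values were seen, was at 0.01 and 27.0 FPKM in DN1d and listed at the lowest value in both ImmV2 libraries. Of the Tgd17 list, 0 of 15 members were called, also 0 when adjusted over the list alone. Of the 14 myeloid genes 0 were called, and 2, Fcer1g and Fcgr3, were higher when adjusted over the list alone (camera adjusted p = 0.206). Without DN1d 1 and 2, 229 and 184 genes were higher and 28 and 25 lower in DN1d, and without ImmV2 1 and 2, 26 and 36 were higher and 137 and 203 lower. The calls of Igkc and Trdv4 ended with a pseudocount of 0.1 FPKM and with the values as deposited, and their adjusted p reached 0.719 and 0.729 in limma over the alternatives.

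DN1e differed from ImmV2 in genes of innate and myeloid cells. It also stood apart across all genes: each other population had its lowest median Spearman correlation with DN1e (0.181 to 0.221). Fcer1g, an adaptor of Fc receptors, was at 700, 278 and 371 FPKM in DN1e and listed at the lowest value in both ImmV2 libraries (adjusted p = 0.00232, limma). Lyz2, a lysozyme of macrophages and granulocytes, was at 406, 290 and 226 FPKM against 0.149 and 0.0329 FPKM (log2 difference 8.10 ± 1.20 SE, adjusted p = 0.00474, limma). Id2, a regulator of innate lymphoid cells, was at 140, 122 and 107 FPKM against 1.79 and 3.70 FPKM (log2 difference 5.09 ± 0.96 SE, adjusted p = 0.021, limma). Of 14 myeloid genes tested, 2 were called higher, and 4 when adjusted over the list alone, adding Ctss and Tyrobp. The myeloid list was higher in DN1e (camera adjusted p = 7.75e-05), with adjusted p = 0.0231 with an estimated correlation. The innate lymphoid list was higher too (camera adjusted p = 0.00417, 1 of 12 called, 2 adjusted over the list alone), with adjusted p = 0.0321 with an estimated correlation. The dendritic and plasmacytoid list had camera adjusted p = 0.025 (0 of 14 called, 1 adjusted over the list alone), with adjusted p = 0.0667 with an estimated correlation. T-lineage commitment factors were lower (camera adjusted p = 0.027, 0 of 12 called, Bcl11b and Ets1 adjusted over the list alone), with adjusted p = 0.389 with an estimated correlation. In total 145 genes were called, 74 higher and 71 lower in DN1e. Without DN1e 1, 2 and 3, 169, 151 and 215 genes were higher and 51, 59 and 68 lower in DN1e, and without ImmV2 1 and 2, 27 and 47 were higher and 188 and 283 lower. Id2 had adjusted p = 0.101 in limma without ImmV2 1. The call of Id2 also ended with a pseudocount of 0.1 FPKM and without ImmV2 1 and DN2 1 together, and those of Id2 and Lyz2 with the values as deposited. Over all alternatives, adjusted p in limma reached 0.352 for Id2 and 0.175 for Lyz2.

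**Figure D3:**
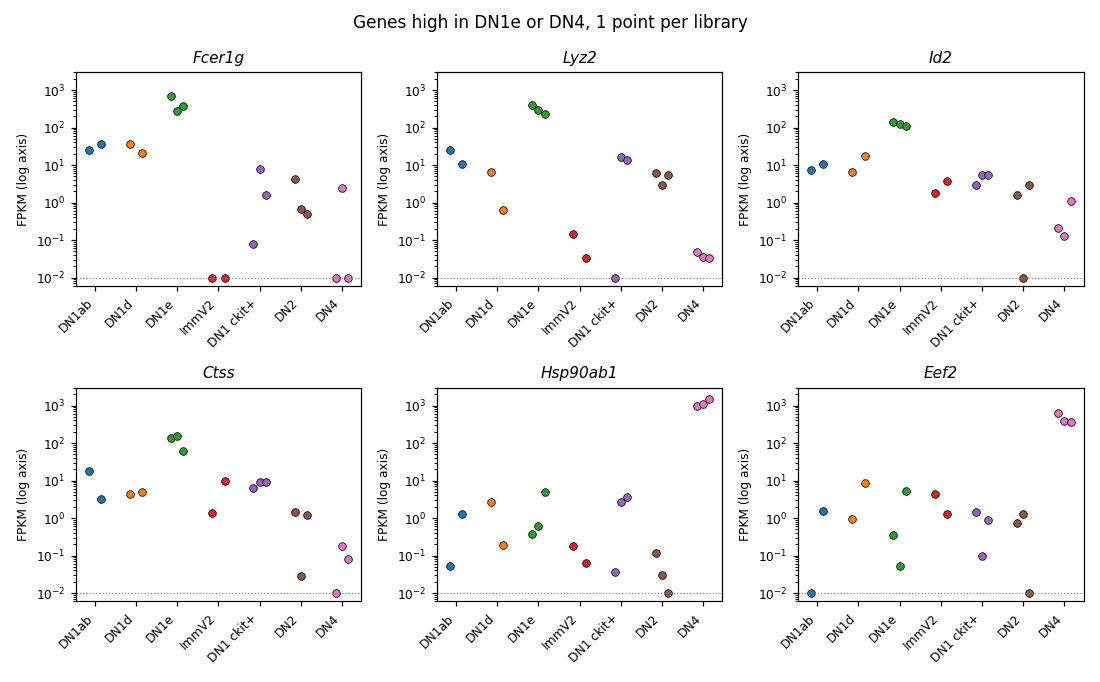
Each point is the FPKM of 1 library on a log axis, for 6 genes in the 7 populations, and the dotted line marks the lowest listed value, 0.01 FPKM. Fcer1g lies at 278 FPKM or more in the DN1e libraries, and Hsp90ab1 at 965 FPKM or more in the DN4 libraries.

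Trgv2 was lower and Lilra6 higher in DN1ab than in ImmV2. The gamma chain variable segment Trgv2 was at 0.01 and 0.0237 FPKM in DN1ab and 122 and 657 FPKM in ImmV2 (log2 difference -8.13 ± 1.30 SE, adjusted p = 0.00853, limma). It was the only 1 of 6 such segments called. Lilra6, an immunoglobulin-like receptor gene, was at 830 and 878 FPKM in DN1ab and 0.457 and 2.39 FPKM in ImmV2 (log2 difference 8.59 ± 1.02 SE, adjusted p = 0.000699, limma). In total 97 genes were called, 52 higher and 45 lower in DN1ab. The TCR complex list was lower (camera adjusted p = 0.0176), with adjusted p = 0.291 with an estimated correlation. Of its 18 members 0 were called, and 3, Cd3d, Cd3e and Themis, when adjusted over the list alone. T-lineage commitment factors were lower (camera adjusted p = 0.0259, 0 of 12 called, 2 adjusted over the list alone), with adjusted p = 0.348 with an estimated correlation. The myeloid list was higher (camera adjusted p = 0.0176, 0 of 14 called, 4 adjusted over the list alone), with adjusted p = 0.266 with an estimated correlation. Of the 14 dendritic and plasmacytoid genes 0 were called, and 1, Pacsin1, was higher when adjusted over the list alone. Without DN1ab 1 and 2, 213 and 260 genes were higher and 29 and 37 lower in DN1ab, and without ImmV2 1 and 2, 36 and 35 were higher and 137 and 201 lower. The call of Lilra6 ended with a pseudocount of 0.1 FPKM and with the values as deposited, and its adjusted p reached 0.446 in limma over the alternatives.

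DN1 ckit+ cells had lower levels of Bcl11b and Cd3e than ImmV2. Bcl11b was at 0.0277, 0.217 and 0.0294 FPKM against 32.8 and 36.6 FPKM (log2 difference -5.03 ± 0.96 SE, adjusted p = 0.0281, limma). Cd3e, a signalling chain of the T cell receptor complex, was at 0.0736, 0.261 and 0.0547 FPKM against 16.6 and 211 FPKM (log2 difference -5.76 ± 1.12 SE, adjusted p = 0.0322, limma). Trgv2 was lower as well, by a log2 difference of -8.06 ± 1.19 SE (adjusted p = 0.00548, limma). It was the only 1 of 6 gamma chain variable segments called, and the others went both ways. Tcrg-V4 was at 57.5, 53 and 90.7 FPKM against 0.01 and 24.7 FPKM. Tcrg-V6 was at 0.01, 0.0465 and 0.01 FPKM against 6.03 and 101 FPKM. Tcrg-V7 was at 5029, 2602 and 2475 FPKM against 20440 and 11.1 FPKM. Esyt1, a membrane-tethering protein gene, was at 70.9, 69.6 and 57 FPKM and listed at the lowest value in both ImmV2 libraries (adjusted p = 0.0056, limma). Kit itself was at 95.6, 49.9 and 141 FPKM against 5.99 and 17.3 FPKM and did not pass (adjusted p = 0.648, limma). In total 81 genes were called, 22 higher and 59 lower in DN1 ckit+. The TCR complex list was lower (camera adjusted p = 0.000727, 1 of 18 called, 4 adjusted over the list alone), with adjusted p = 0.209 with an estimated correlation. T-lineage commitment factors were lower (camera adjusted p = 0.0486, 1 of 12 called, 2 adjusted over the list alone), with adjusted p = 0.412 with an estimated correlation. Without DN1 ckit+ 1, 2 and 3, 29, 42 and 30 genes were higher and 25, 36 and 27 lower in DN1 ckit+, and without ImmV2 1 and 2, 13 and 21 were higher and 193 and 280 lower. The values as deposited gave 8 higher and 4 lower. In limma, Bcl11b had adjusted p = 0.0937, 0.0613 and 0.0814 without DN1 ckit+ 1, 2 and 3 and 0.0684 and 0.0641 without ImmV2 1 and 2, and Cd3e had 0.0977, 0.0652 and 0.0894 without DN1 ckit+ 1, 2 and 3 and 0.168 without ImmV2 2. Both calls also ended with the values as deposited, that of Cd3e with a pseudocount of 5 FPKM and that of Bcl11b without ImmV2 1 and DN2 1, and their adjusted p reached 0.18 for Bcl11b and 0.388 for Cd3e in limma over the alternatives.

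Dio3, Traj35 and Pcolce2 were lower in DN2 than in ImmV2. Dio3 was at 0.01, 0.01 and 0.0162 FPKM in DN2 and 333 and 119 FPKM in ImmV2 (log2 difference -7.63 ± 0.76 SE, adjusted p = 0.000503, limma). The alpha chain joining segment Traj35 was at 0.01, 12.6 and 0.01 FPKM against 1794 and 279 FPKM (log2 difference -8.20 ± 1.13 SE, adjusted p = 0.00486, limma). Traj32 and Traj53 had the same 279 FPKM in ImmV2 2, and how many fragments stand behind such values is unknown. Pcolce2 was at 0.01, 0.01 and 0.228 FPKM against 156 and 85.9 FPKM (log2 difference -6.76 ± 1.09 SE, adjusted p = 0.0146, limma). In total 46 genes were called, 3 higher and 43 lower in DN2. The Tgd17 list was lower in DN2 (camera adjusted p = 0.0256), with adjusted p = 0.108 with an estimated correlation. Of its 15 members 0 were called, and 3, including Maf, when adjusted over the list alone. Maf was at 0.585, 0.123 and 0.127 FPKM in DN2 against 39 and 40.7 FPKM. Lower members were not particular to DN2. Against the same ImmV2 libraries, 3 were lower in DN1 ckit+, 2 in DN1ab, 1 in DN1e and 1 in DN4 when adjusted over the list alone. The TCR complex list was lower (camera adjusted p = 0.0256, 0 of 18 called, 5 adjusted over the list alone), with adjusted p = 0.454 with an estimated correlation. Without DN2 1, 2 and 3, 24, 17 and 13 genes were higher and 33, 33 and 26 lower in DN2, and without ImmV2 1 and 2, 3 and 5 were higher and 184 and 253 lower. The values as deposited gave 6 higher and 3 lower. The calls of Pcolce2 and Traj35 ended with the values as deposited, and that of Pcolce2 also with a pseudocount of 0.1 FPKM and without ImmV2 1 and DN2 1, with adjusted p up to 0.253 for Pcolce2 and 0.407 for Traj35 in limma over the alternatives.

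DN4, the latest double-negative stage, had higher levels of Hsp90ab1 and Eef2 than ImmV2. The chaperone gene Hsp90ab1 was at 965, 1081 and 1521 FPKM in DN4 and 0.18 and 0.0615 FPKM in ImmV2 (log2 difference 10.03 ± 1.04 SE, adjusted p = 0.000266, limma). The elongation factor gene Eef2 was at 640, 386 and 358 FPKM against 4.24 and 1.26 FPKM (log2 difference 7.02 ± 1.09 SE, adjusted p = 0.00857, limma). Every cell uses both genes, yet in all libraries outside DN4 Hsp90ab1 was at 4.88 FPKM or less and Eef2 at 8.69 FPKM or less. The reduction to 1 row per symbol may thus contribute to these differences, which was not settled. Pcolce2 was lower, by a log2 difference of -6.74 ± 1.09 SE (adjusted p = 0.0108, limma). In total 61 genes were called, 17 higher and 44 lower in DN4. The cell cycle list was higher (camera adjusted p = 0.00162), with adjusted p = 0.492 with an estimated correlation. Of its 25 members 0 were called, also 0 when adjusted over the list alone, and their median log2 difference was 1.78. The double-positive transition list was higher (camera adjusted p = 0.0251, 0 of 10 called), with adjusted p = 0.312 with an estimated correlation. Adjusted over the list alone, 2 passed, the recombinase genes Rag1 (59.1, 53.9 and 59.6 FPKM in DN4, 0.01 and 0.662 FPKM in ImmV2) and Rag2. Without DN4 1, 2 and 3, 40, 27 and 34 genes were higher and 31, 25 and 26 lower in DN4, and without ImmV2 1 and 2, 17 and 19 were higher and 184 and 262 lower. The values as deposited gave 10 higher and 5 lower. The calls of Hsp90ab1, Eef2 and Pcolce2 ended with the values as deposited, and those of Eef2 and Pcolce2 with a pseudocount of 0.1 FPKM, with adjusted p up to 0.132, 0.522 and 0.276 in limma over the alternatives.

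DN1d was also compared with DN1 ckit+ cells of the same stage. Bcl11b, Cd3e and Trgv2 were higher in DN1d. Bcl11b was at 22.2 and 61.9 FPKM against 0.0277, 0.217 and 0.0294 FPKM (log2 difference 5.13 ± 0.96 SE, adjusted p = 0.0246, limma). Cd3e was at 117 and 51.6 FPKM against 0.0736, 0.261 and 0.0547 FPKM (log2 difference 6.13 ± 1.12 SE, adjusted p = 0.0208, limma). Trgv2 was at 117 and 204 FPKM against 0.01, 0.202 and 0.01 FPKM (log2 difference 7.18 ± 1.19 SE, adjusted p = 0.0109, limma). It was the only 1 of 6 gamma chain variable segments called, and uncalled segments went both ways. Tcrg-V7 was at 11.4 and 0.01 FPKM in DN1d against 5029, 2602 and 2475 FPKM. Tcrg-V4 was far higher in DN1d, at 13160 and 26620 FPKM against 57.5, 53 and 90.7 FPKM. It was also at 13160 FPKM in DN2 1. The immunoglobulin gene Igkc was higher too, at 843 and 1205 FPKM in DN1d and listed at the lowest value in every DN1 ckit+ library (adjusted p = 0.00214, limma). Adjusted over the list alone, 1 of 14 myeloid genes, Fcgr3, and 1 of 9 thymic epithelium genes, Cdh1, were higher, with 0 called. The B cell list had camera adjusted p = 0.0616 (0 of 10 called, also 0 adjusted over the list alone), with adjusted p = 0.14 with an estimated correlation. In total 89 genes were called, 70 higher and 19 lower in DN1d. Of the 15 Tgd17 genes tested 0 were called, and 2, including Maf, were higher when adjusted over the list alone. Of the 15 early progenitor genes 0 were called, and 2, Kit and Flt3, were lower when adjusted over the list alone. T-lineage commitment factors went both ways, with 1 of 12 called, Bcl11b (camera adjusted p = 0.28). Adjusted over the list alone, 3, Bcl11b, Ets1 and Runx3, were higher and 1, Gata3, was lower. The TCR complex list was higher (camera adjusted p = 0.0323, 1 of 18 called, 1 adjusted over the list alone), with adjusted p = 0.14 with an estimated correlation. Without DN1d 1 and 2, 313 and 262 genes were higher and 20 and 17 lower in DN1d, and without DN1 ckit+ 1, 2 and 3, 38, 42 and 43 were higher and 32, 47 and 37 lower. The values as deposited gave 6 higher and 6 lower. In limma, Bcl11b had adjusted p = 0.0762, 0.0574 and 0.0686 without DN1 ckit+ 1, 2 and 3 and 0.0961 without DN1d 2, and Cd3e had 0.0644 and 0.0604 without DN1 ckit+ 1 and 3 and 0.0701 without DN1d 1. Both calls ended with the values as deposited and that of Cd3e with a pseudocount of 5 FPKM, with adjusted p up to 0.212 for Bcl11b and 0.124 for Cd3e in limma over the alternatives.

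Between the DN1 subsets DN1e and DN1d, Lyz2 and Cst3 were higher and Trdv4 lower in DN1e. Lyz2 was at 406, 290 and 226 FPKM against 6.38 and 0.648 FPKM (log2 difference 6.42 ± 1.20 SE, adjusted p = 0.0199, limma). Cst3, a protease inhibitor gene abundant in myeloid cells, was at 230, 120 and 181 FPKM and listed at the lowest value in both DN1d libraries (adjusted p = 0.0125, limma). Trdv4 was lower in DN1e, at 0.388, 0.01 and 0.01 FPKM against 19.6 and 32.8 FPKM (log2 difference -4.55 ± 0.55 SE, adjusted p = 0.00206, limma). Sox13 was at 0.0425, 0.01 and 3.59 FPKM in DN1e and 14 and 76.3 FPKM in DN1d and did not pass over all genes (adjusted p = 0.19, limma). In total 147 genes were called, 67 higher and 80 lower in DN1e. The myeloid list was higher (camera adjusted p = 0.0308, 1 of 14 called), with adjusted p = 0.249 with an estimated correlation. Adjusted over the list alone, 4 of its members were higher and 1, Fcgr3, was lower, and of the 14 dendritic and plasmacytoid genes 1, Batf3, was higher, with 0 called. Of the 15 Tgd17 genes 0 were called, and 2, including Sox13, were lower when adjusted over the list alone. Of the 12 T-lineage commitment factors 1, Ets1, was called lower, and 2, Bcl11b and Ets1, when adjusted over the list alone. Ets1 was listed at the lowest value in every DN1e library and at 56.6 and 111 FPKM in DN1d, with an adjusted p that rounds to 0.05 (limma). Without DN1e 1, 2 and 3, 168, 137 and 210 genes were higher and 77, 65 and 81 lower in DN1e, and without DN1d 1 and 2, 39 and 29 were higher and 294 and 244 lower. Lyz2 had adjusted p = 0.125 in limma without DN1d 2. Ets1 had adjusted p = 0.0842 and 0.182 without DN1d 1 and 2 and 0.0769, 0.0873 and 0.0715 without DN1e 1, 2 and 3 in limma, and its call held in 3 of 17 alternatives. The calls of Lyz2 and Trdv4 ended with the values as deposited and that of Lyz2 also with a pseudocount of 0.1 FPKM. Over all alternatives, adjusted p in limma reached 0.364 for Lyz2 and 0.458 for Trdv4.

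DN1ab and DN1 ckit+ cells differed in Ripk4, Lilra6 and Tshb, while Bcl11b was low in both. Bcl11b was at 0.202 and 0.203 FPKM in DN1ab and 0.0277, 0.217 and 0.0294 FPKM in DN1 ckit+ (adjusted p = 1, limma). Ripk4, a protein kinase gene, was at 97.7 and 46.5 FPKM in DN1ab and 0.0266, 0.01 and 0.0281 FPKM in DN1 ckit+ (log2 difference 6.07 ± 0.60 SE, adjusted p = 0.00011, limma). Lilra6 was higher in DN1ab, by a log2 difference of 9.03 ± 0.93 SE (adjusted p = 0.000157, limma). Tshb, a thyrotropin subunit gene, was listed at the lowest value in both DN1ab libraries and at 16.5, 19.7 and 23 FPKM in DN1 ckit+ (adjusted p = 0.00278, limma). In total 73 genes were called, 56 higher and 17 lower in DN1ab. Of the 15 early progenitor genes 0 were called, and 1, Cd34, was lower when adjusted over the list alone. Of the 14 myeloid genes 0 were called, and 3, Fcer1g, Mpo and Tyrobp, were higher when adjusted over the list alone (camera adjusted p = 0.376), as was 1 of the 9 thymic epithelium genes, Foxn1. Without DN1ab 1 and 2, 239 and 316 genes were higher and 12 and 20 lower in DN1ab, and without DN1 ckit+ 1, 2 and 3, 37, 43 and 41 were higher and 29, 35 and 34 lower. The values as deposited gave 14 higher and 15 lower. The call of Lilra6 ended with the values as deposited.

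From DN1 ckit+ to DN2, the step at which T-lineage genes come on, few genes were called. The count rose to between 25 and 48 with any 1 library left out, so it does not measure how alike the stages are. Tshb was at 0.01, 0.01 and 0.0575 FPKM in DN2 and 16.5, 19.7 and 23 FPKM in DN1 ckit+ (log2 difference -4.33 ± 0.56 SE, adjusted p = 0.00388, limma). The vomeronasal receptor gene Vmn1r179 was lower in DN2, by a log2 difference of -4.54 ± 0.60 SE (adjusted p = 0.00498, limma). Bcl11b was at 13.3, 17.9 and 18.9 FPKM in DN2 against 0.0277, 0.217 and 0.0294 FPKM and did not pass over all genes (adjusted p = 0.115, limma), while it passed without the filter and without the trend. In total 15 genes were called, 4 higher and 11 lower in DN2. Of the 12 T-lineage commitment factors 0 were called, and 2, Bcl11b and Ets1, were higher when adjusted over the list alone. Without DN2 1, 2 and 3, 31, 17 and 20 genes were higher and 9, 8 and 10 lower in DN2, and without DN1 ckit+ 1, 2 and 3, 3, 4 and 2 were higher and 38, 44 and 37 lower. The calls of Tshb and Vmn1r179 ended with the values as deposited and that of Vmn1r179 with a pseudocount of 0.1 FPKM, with adjusted p up to 0.131 and 0.161 in limma over the alternatives.

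From DN2 to DN4, Cd3e was higher in DN4, at 170, 105 and 166 FPKM against 0.136, 0.01 and 0.83 FPKM (log2 difference 6.82 ± 1.00 SE, adjusted p = 0.00741, limma). Hsp90ab1 was higher by a log2 difference of 10.12 ± 0.93 SE (adjusted p = 0.00014, limma) and Eef2 by 8.14 ± 0.98 SE (adjusted p = 0.00117, limma). The importin gene Ipo4 was at 52.5, 65.4 and 33.3 FPKM against 0.01, 0.0195 and 0.0256 FPKM (log2 difference 5.61 ± 0.66 SE, adjusted p = 0.00117, limma). Kit was at 1.63, 2.92 and 0.563 FPKM in DN4 and 13.9, 60.3 and 106 FPKM in DN2 and did not pass over all genes (adjusted p = 0.492, limma). In total 20 genes were called, 18 higher and 2 lower in DN4. The TCR complex list was higher (camera adjusted p = 0.000189), with adjusted p = 0.141 with an estimated correlation. Of its 18 members 1 was called, Cd3e, and 2, Cd3e and Themis, when adjusted over the list alone. T-lineage commitment factors were higher (camera adjusted p = 0.0244, 0 of 12 called, also 0 adjusted over the list alone), with adjusted p = 0.454 with an estimated correlation. Without DN4 1, 2 and 3, 55, 35 and 44 genes were higher and 1, 4 and 4 lower in DN4, and without DN2 1, 2 and 3, 16, 20 and 19 were higher and 27, 20 and 26 lower. The call of Eef2 ended with the values as deposited.

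The other lists passed camera's test in none of the 11 comparisons, and 0 of their members were called. Their lowest camera adjusted p was 0.189 for HMG-box factors, 0.604 for type 1 and cytotoxic effector genes, 0.0755 for early progenitor genes, 0.408 for Notch targets and 0.0616 for TCR signal-induced genes. It was 0.107 for trafficking receptors, 0.352 for erythroid genes, 0.123 for thymic epithelium and 0.152 for immediate early and stress genes. Adjusted over the list alone, calls over the 11 comparisons numbered 7 for HMG-box factors, 8 for early progenitor genes, 3 for TCR signal-induced genes, 12 for trafficking receptors and 2 for thymic epithelium, and 0 for the other lists named here.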

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

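The alternatives were planned before the data were examined, except the values as deposited and the fit without ImmV2 1 and DN2 1, the libraries with the most rows at the lowest value, which were chosen after seeing the data. No called gene named by the rule reversed under any alternative run. Calls were often lost: of 128 such calls, 67 held without each single library in turn, 75 with the replicate block, 71 with a pseudocount of 0.1 and 38 with the values as deposited. Key genes that were not called passed in 30 of 3054 recomputed results. Total counts not given here stayed within 1.5 times those reported, while the numbers higher and lower moved further in many cases, and the cause of the moves was not tested unless stated. Unknown depth limits how far low values can be read.

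With a pseudocount of 0.1 the counts were 16 for DN1d vs ImmV2, 35 for DN1ab vs ImmV2, 38 for DN1 ckit+ vs ImmV2, 21 for DN2 vs ImmV2, 30 for DN4 vs ImmV2, 46 for DN1d vs DN1 ckit+, 85 for DN1e vs DN1d, 4 for DN2 vs DN1 ckit+, 13 for DN4 vs DN2 and 226 for the F test. A pseudocount of 5 gave 25 for DN2 vs DN1 ckit+. With no filter the count was 23 for DN2 vs DN1 ckit+. With at least 5 FPKM in 2 libraries, which tests fewer genes, it was 36 for DN1d vs ImmV2, 29 for DN2 vs ImmV2, 46 for DN1d vs DN1 ckit+ and 84 for DN1e vs DN1d. Without the trend it was 44 for DN2 vs DN1 ckit+, and with median scaling 9 for DN2 vs DN1 ckit+, split 1 higher and 8 lower against 4 and 11. Values as deposited gave 8 (5 higher, 3 lower) for DN1d vs ImmV2, 46 (22 higher, 24 lower) for DN1e vs ImmV2, 29 (17 higher, 12 lower) for DN1ab vs ImmV2, 12 (8 higher, 4 lower) for DN1 ckit+ vs ImmV2, 9 (6 higher, 3 lower) for DN2 vs ImmV2, 15 (10 higher, 5 lower) for DN4 vs ImmV2, 12 (6 higher, 6 lower) for DN1d vs DN1 ckit+, 24 (9 higher, 15 lower) for DN1e vs DN1d, 29 (14 higher, 15 lower) for DN1ab vs DN1 ckit+, 1 (0 higher, 1 lower) for DN2 vs DN1 ckit+, 11 (10 higher, 1 lower) for DN4 vs DN2 and 146 for the F test. Without ImmV2 1 and DN2 1 the counts were 186 (30 higher, 156 lower) for DN1d vs ImmV2, 188 (36 higher, 152 lower) for DN1ab vs ImmV2, 199 (10 higher, 189 lower) for DN1 ckit+ vs ImmV2, 174 (16 higher, 158 lower) for DN2 vs ImmV2, 197 (16 higher, 181 lower) for DN4 vs ImmV2, 47 (36 higher, 11 lower) for DN2 vs DN1 ckit+ and 52 (22 higher, 30 lower) for DN4 vs DN2, and DN1e vs ImmV2 had 21 higher and 193 lower. With only the libraries of the 2 populations in the fit, and so fewer samples to estimate the spread, limma called 0 genes in 9 comparisons (1043 to 1830 at an unadjusted p under 0.05), 30 for DN2 vs DN1 ckit+ and 9 for DN4 vs DN2. Camera's tests passed for 18 of 198 pairs of list and comparison, and for 2 with an estimated correlation.

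Leaving out each library in turn gave counts of 163 to 257 for DN1d vs ImmV2, 210 to 330 for DN1e vs ImmV2, 173 to 297 for DN1ab vs ImmV2, 54 to 301 for DN1 ckit+ vs ImmV2, 39 to 258 for DN2 vs ImmV2, 52 to 281 for DN4 vs ImmV2, 70 to 333 for DN1d vs DN1 ckit+, 202 to 333 for DN1e vs DN1d, 66 to 336 for DN1ab vs DN1 ckit+, 25 to 48 for DN2 vs DN1 ckit+, 39 to 56 for DN4 vs DN2 and 247 to 499 for the F test. Where this left 1 library in a population, that population added nothing to the estimate of the spread. It was assumed to vary like the other groups. A gene at the lowest value in the other populations could then be called from that 1 library alone. How many of the moves arose so was not tested.

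No pairing by replicate number was seen. The deviations of same-numbered libraries from their population means correlated between -0.0164 and 0.0174 (48 pairs). Those of differently numbered libraries correlated between -0.0224 and 0.0224 (90 pairs). Replicate libraries agreed poorly, so a shared animal or day could go unseen. With the replicate block the counts were 33 for DN1d vs ImmV2, 69 for DN1e vs ImmV2, 63 for DN1ab vs ImmV2, 33 for DN1 ckit+ vs ImmV2, 16 for DN2 vs ImmV2, 31 for DN4 vs ImmV2, 57 for DN1d vs DN1 ckit+, 67 for DN1e vs DN1d, 47 for DN1ab vs DN1 ckit+, 9 for DN2 vs DN1 ckit+ and 169 for the F test, and the block changed no camera call. It ended the calls of Bcl11b and Cd3e in DN1 ckit+ vs ImmV2, Id2 in DN1e vs ImmV2, Lyz2 and Ets1 in DN1e vs DN1d and Pcolce2 in DN2 vs ImmV2, among others. The choice among several rows of a symbol was not run, since each symbol had 1 row.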

Other observations

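The transcript-number test of replicate agreement was written down before its result was seen. The test by mean level, the tests of the DN4 and DN1e patterns and the splits of libraries were chosen after the results they measure had been seen at least in part, and how the bounds of the correlation tests were read was settled after their values were known. An earlier reading, with the most extreme pair set against the lower bound, would have left both correlation tests undecided.

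Of 39 alpha chain joining segments tested, 5 were lower in DN1e and 5 in DN1 ckit+ than in ImmV2, 3 in DN4, 2 in DN1ab, 2 in DN2 and 1 in DN1d (limma), with the ImmV2 libraries shared by these comparisons. Traj35 was at 1794 and 279 FPKM in the ImmV2 libraries and listed at the lowest value in every other library except DN2 2, at 12.6 FPKM. Traj53 was at 1294 and 279 FPKM in ImmV2 and 618 and 36 FPKM in DN1d. It was at 1.61 FPKM in DN1 ckit+ 2 and listed at the lowest value in the other libraries. The delta segment Trdv4 was at 19.6 and 32.8 FPKM in DN1d and under 1 FPKM in every other library. The enrichment of such segments was not tested, and others were high elsewhere, such as Traj42 at 8277 FPKM in DN1d 2 and at the lowest value in both ImmV2 libraries. Short segments share sequence with relatives, so their levels are uncertain. Several also shared 1 value within a library, such as Traj35 and Traj58 at 1794 FPKM in ImmV2 1. Traj32, Traj35 and Traj53 were all at 279.1 FPKM in ImmV2 2. Without counts, such values may rest on few fragments, which was not tested.

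Replicate libraries ranked genes differently, with a median Spearman correlation of 0.325 within populations. One candidate explanation is that 1 transcript stood for each gene symbol. It needed genes with 1 annotated transcript to agree better, by at least 0.2, than genes with 4 or more. The difference was 0.00169 over 6427 genes of each kind matched on mean, and single pairs ranged from -0.0768 to 0.067, short of that bound. Transcript numbers came from an annotation of another build than mm8. The kinds of gene were matched on mean alone and may differ otherwise, so the result does not exclude the explanation. Losses of low transcripts from small RNA input needed a rise of at least 0.3 from the lowest to the highest of 4 bins of mean level. The rise was 0.0865, with pairs from 0.0267 to 0.124, short of that bound. It was not steady, at 0.140, 0.112, 0.105 and 0.226 from the lowest bin up. Levels spanned a wider range in the highest bin, so the bins decide little. Low values also occurred in genes listed high in another library of the same population. Where a gene of 1 annotated transcript reached 50 FPKM in a library, another of that population was under 1 FPKM in 64.5% of 4768 cases. With 4 or more transcripts the share was 51.2% of 6432. Cases were picked by their highest library, so 50 FPKM in 1 library need not mark an abundant transcript. These shares thus cannot decide whether losses were confined to low transcripts. Losses at every level stay open as well, and their cause was not tested.

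Hsp90ab1, Eef2, Vdac1 and Cd3e were among 6 called genes at 50 FPKM or more in every DN4 library and under 5 FPKM in every DN2 library. Cd3e is a T cell gene, while Hsp90ab1 and Eef2 are used by every cell, so a choice among transcripts may contribute. Of the 5 such genes with a transcript number, 80% had 4 or more annotated transcripts, 22.8 percentage points above the share at like mean level. With 5 genes this decides nothing, and a difference between the stages stays open as well.

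Fcer1g and Lyz2 were higher in DN1e than in ImmV2, and myeloid cells inside the sorted gate are a candidate explanation. Of 12 abundant macrophage transcripts, 6 of them also in the myeloid list, 5 were above the median of every other population in each DN1e library. They were C1qa, Lyz2, Fcer1g, Ctss and Cst3, and all 5 were also above every library outside DN1e. Of 7672 genes reaching 50 FPKM in any library, a level that Csf1r and Apoe never reached, 2.76% were above the medians in this way. C1qb was at 0.01, 409 and 325 FPKM in DN1e, while Csf1r stayed at 0.0837 FPKM or less and Apoe at 5.92 FPKM or less. Lyz2, Fcer1g, Ctss and Cst3 had been seen to be higher in DN1e before the count was made, and Actb itself was under 1 FPKM in each DN1e library, so neither the count nor the low genes decide, and such cells cannot be told apart from myeloid gene expression by DN1e cells, which was not tested.

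As for chance, 1 of 100 groupings of the 18 libraries, the real one, gave as many as the 343 genes of the F test. The highest of the others gave 97. The total was thus larger than the random groupings of these libraries gave. Since a random grouping could give 97 genes, the test speaks for the total and for none of the 343 genes singly. Of the 10 splits of the 6 libraries, the real one gave 15 genes for DN2 vs DN1 ckit+ and the highest other gave 6. For DN4 vs DN2 the real split gave 20 genes and the highest other 15. In each of these pairs 1 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05.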
